A study of Mus musculus with 4 samples.

How the data were processed

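Spatial transcriptomes of 4 mouse liver sections were compared, 1 section for each of 4 diets. Per the labels, the mice were male C57BL/6J animals fed a normal diet (ND), a high-fat diet (HFD), a high-fat diet with spontaneously fermented kimchi (S-K), or a high-fat diet with kimchi fermented with a Leuconostoc mesenteroides starter (LMS-K). Per the labels' protocols, the libraries came from the Visium workflow with its mouse transcriptome probe set, in which pairs of probes hybridise to transcripts and are counted under spatially barcoded spots. A spot is a small region that holds several cells, so every value describes a region of tissue and not a cell type.

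The authors deposited, for each section, a matrix of whole-number UMI counts per gene and spot, not normalized, with the positions of the spots. Per the file headers, the counts were made with Space Ranger 2.0.1. Per the submitters' processing notes, the genome build was mm10. The settings of the probe alignment and any probe filter are not given in the sources used here. The deposited summary of each library gives fractions of reads (sequencing saturation, base quality, reads on filtered probes), which are printed here as percentages, and counts of reads and genes. A matrix listed under a second name for each section held the same entries line by line and was not used as a second measurement. The tables used here list 19465 features, and none of them is a mitochondrially encoded gene or a gene of the ribosomal protein list.

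Spots in tissue with at least 500 UMIs were kept, which left out 3 spots of ND and 1 spot of each other section. UMIs were summed over the kept spots of a section and scaled to CPM, the unit in which every section has the same total. The kept spots held 77851254 UMIs in ND, 104507028 in HFD, 75084042 in S-K and 69917423 in LMS-K, so that a count of 3, the upper limit that a count of 0 allows, stood for 0.0385, 0.0287, 0.04 and 0.0429 CPM. At these depths the 95% intervals of the genes named by size reached at most 0.42 log2 units to either side of the ratio. Each comparison is the log2 ratio of CPM between 2 sections. Its interval is an exact conditional binomial (Clopper-Pearson) interval at 95% on the 2 counts, and the interval of a single CPM value is an exact Poisson interval. Both cover counting error only. Because each diet has 1 section, no test between diets is possible and no p-value is given, and no difference between diets has a replicate check. Each section was also divided into 4 quadrants of about equal spot number, and the range of a gene over the quadrants describes the spread inside a section, not the spread between animals.

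The rules for reporting were fixed before the data were examined. Genes with at least 10 CPM in either section were counted as higher or lower when the CPM differed at least 2-fold. Genes were named by size: among genes with at least 20 CPM in either section whose quadrant ranges did not overlap, the 8 highest and 8 lowest ratios of a comparison (6 and 6 for LMS-K over S-K). In addition, 2 to 4 members with the highest absolute log2 ratio were named from each gene list described. Gene lists covered lipid, cholesterol, bile acid, xenobiotic, glucose and amino acid metabolism, acute phase, interferon and antigen presentation, inflammation, matrix, oxidative stress, endoplasmic reticulum (ER) stress, sex-biased, clock, early-response and proliferation genes, and markers of liver cell types. For each list the median log2 ratio over members with a mean of at least 5 CPM is given, with how many members differed at least 1.5-fold, and with the percentile of the median among 10000 random lists of the same size matched on mean expression. Lists with fewer than 3 such members have no median. The percentile describes these libraries and is not a test between diets. Genes named outside these rules are said to have been chosen after their values were seen. Genes of families with closely related sequences (Mup, Cyp, Serpina, Orm, H2, Acot, Slco1a, Ugt and Mt genes) are uncertain, because a probe can take transcripts of a relative.

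The share of the HFD over ND difference left in a kimchi section is the median, over genes at least 2-fold apart between HFD and ND, of the log2 ratio of that section over ND divided by the log2 ratio of HFD over ND. Because both ratios share ND and the genes were selected on HFD, the share was also computed in 20 simulations in which the 3 fat-fed sections scatter around 1 common profile with their own observed spread, and with the selection made on each other section. The comparisons of S-K and of LMS-K with ND were added after seeing the data.

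For position along the portal-to-central axis of the liver lobule, each spot was scored by the mean z score of central landmark genes minus that of portal landmark genes, computed within its section from log-transformed UMIs per 10000. Of 16 landmark genes fixed beforehand, 14 are in the tables. Spots were divided into 5 zones of equal spot number, zone 1 the most portal and zone 5 the most central. Gradients are log2 CPM in zone 5 over zone 1 and were read in lists of zonation genes held out from the score. Genes were compared between zones when they reached 50 CPM in zone 1 or zone 5 of both sections.

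The steps were run on simulated counts drawn with the real means and library sizes. With 200 genes changed in a simulated comparison of HFD over ND, 100% of 100 genes changed 2.5-fold and 100% of 100 genes changed 4-fold were found at least 2-fold apart, 0 of 6367 unchanged genes were, and 94.8% of intervals over 6567 genes held the true ratio. Of 300 random lists in that simulation, 6% fell outside the central 95% of matched lists. The simulated comparison held counting error only, with no spread between animals, sections or libraries. At these depths such results follow largely from the design. They check the calculation and not how reliable a difference between diets is. For simulated spots of the ND section, the zone score correlated with the true position at r = 0.906 over 3059 spots, and the gradients of 43 held-out genes were a median 0.910 of those by true position.

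The alternatives tried were edgeR's TMM factors and DESeq2's median-of-ratios factors over the 4 sections, used for scaling only, totals without the 50 most abundant genes, no filter or a filter of 50 CPM on genes, all spots, spots with at least 3000 UMIs, spots with 6 neighbours in tissue, equal weight for each spot, sections thinned to the shallowest total, and pooled zones of equal weight. For zones, the alternatives were 3 zones, scores averaged with neighbouring spots, odd or even landmarks, pooled limits between zones and spots thinned to 3000 UMIs. Alternatives chosen after seeing the data were TMM factors from genes at 10 CPM or more, sections without the 5% of spots richest in smooth muscle genes, and tables without genes of large families. Coordinates were copied from a RefSeq gene table of assembly GRCm38.p6, the assembly that UCSC calls mm10, for 55 of 55 named genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 were used.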

Results

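Gene expression was mapped in 1 liver section from each of 4 diets: a normal diet (ND), a high-fat diet (HFD), and the high-fat diet with spontaneously fermented kimchi (S-K) or with kimchi made with a Leuconostoc mesenteroides starter (LMS-K). The comparisons ask how the liver of a mouse on the high-fat diet differs from that of a mouse on the normal diet, how each kimchi section differs from the high-fat section, how the kimchi sections differ from each other, and where along the axis from portal tract to central vein these differences lie. The kept spots numbered 3059 in ND, 3711 in HFD, 2966 in S-K and 2759 in LMS-K. The median spot held 24484, 27103, 24189.5 and 24606 UMIs and 4184, 4559, 4282.5 and 4342 genes, in the same order. Sections held between 69917423 and 104507028 UMIs, so counting error was small, and intervals given here are 95% intervals that cover counting error only. There were no replicates, and each difference is a difference between 2 sections.

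By several measures the libraries fell into pairs. Over 4413 genes at a mean of 10 to 50 CPM, the correlation of log2 CPM across genes, which are not independent replicates, was 0.877 between ND and LMS-K and 0.889 between HFD and S-K, against 0.754 to 0.855 for the other pairs of sections. Sequencing saturation was 28.9% in ND and 27.8% in LMS-K, against 20.8% in both HFD and S-K. Other measures did not follow the pairs: reads on filtered probes made up 86% in ND, 84.1% in HFD and 83.1% in LMS-K but 75.5% in S-K, and over 6010 genes at 0.05 to 0.3 CPM HFD correlated with LMS-K at 0.505 and with S-K at 0.486. The 1306 chemosensory, keratin-associated protein and defensin genes, taken here as not expressed in liver, summed to 311 CPM (307 to 315) in ND and 317 CPM (313 to 321) in LMS-K. They summed to 160.0 CPM (158 to 163) in HFD and 129 CPM (127 to 132) in S-K. S-K over HFD lies within a pair, whereas HFD over ND, LMS-K over HFD and LMS-K over S-K cross the pairs. For HFD over ND, the within-pair ratio LMS-K over ND is therefore given beside the main gene groups.

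In the HFD section, many genes of cholesterol synthesis, of antigen presentation and the interferon response, of the ER stress response and of Kupffer cells, the resident macrophages of the liver, were higher than in the ND section. Several genes of amino acid breakdown and the urea cycle and several of xenobiotic metabolism were lower, as was Scd1, the desaturase that forms monounsaturated fatty acids. Many genes known as male-biased in mouse liver were higher and several female-biased genes lower, although both mice were male. Of 6842 genes with at least 10 CPM in either section, 154 were at least 2-fold higher and 54 at least 2-fold lower in HFD, and 89.8% lay within 1.5-fold. Pairs of quadrants within a section differed this much in 0 to 4 genes in ND and in 0 or 1 gene in HFD.

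Among genes with at least 20 CPM in either section and quadrant ranges that did not overlap, from which genes are named by size, the highest ratio was that of Derl3, a component of ER-associated protein degradation (ENSMUSG00000009092, chromosome 10, 75893398 to 75895941, GRCm38.p6), with 28.8 CPM in HFD and 0.668 CPM in ND (log2 ratio 5.43, 5.03 to 5.85). Selenbp2, a male-biased selenium-binding protein gene (ENSMUSG00000068877, chromosome 3, 94693573 to 94704406), followed with 233.8 and 18.2 CPM (3.68, 3.61 to 3.76). Also among the highest ratios were the acute phase gene Orm2 (2.93), the steroid dehydrogenase genes Hsd17b6 (2.89) and Hsd3b5 (2.88), Klhdc7a (2.78), the ER chaperone partner Sdf2l1 (2.52) and Serpina7 (41.2 against 7.31 CPM), which encodes thyroxine-binding globulin. The lowest ratios were those of the uncharacterised transcript E030018B13Rik (-4.67) and Cyp17a1, a steroid hydroxylase (-3.35). Scd1 (chromosome 19, 44394450 to 44407709) stood at 72.9 CPM in HFD and 539 CPM in ND (-2.89, -2.92 to -2.85), and Cyp3a11, a main drug-metabolising cytochrome P450, at 402 and 2910 CPM (-2.86). Apoa4 (-2.25), the transaminase gene Got1 (-2.25), the glucocorticoid-induced Fkbp5 (-2.24) and the transporter gene Slco1a4 (-2.16) completed this group.

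In the cholesterol synthesis list, 12 of 21 measured genes were at least 1.5-fold higher in HFD and 0 lower. The median log2 ratio was 0.69, at percentile 100 of the 10000 random lists. Sqle, the squalene epoxidase, led the list with 10.7 CPM against 0.514 CPM (4.38), followed by Cyp51 (2.32), Msmo1 (67.3 against 16.9 CPM) and Stard4 (1.91). The within-pair median of LMS-K over ND was 0.95. Of 26 interferon and antigen presentation genes, 19 were higher and 0 lower (median 1.19, percentile 100, within-pair 0.88), led by the chemokine gene Cxcl9 (2.25) and the MHC class II genes H2-Eb1 (2.11), H2-Ab1 (2.03) and H2-Aa (1.74). The Kupffer cell markers were higher in 9 of 10 cases (median 0.96, percentile 100, within-pair 0.82), among them Marco (1.24) and the complement genes C1qc (1.13), C1qb (1.04) and C1qa (1.03). Markers of other non-parenchymal cells lay nearer to ND, with medians of 0.33 for sinusoidal endothelium (4 of 12 higher) and 0.26 for stellate cells (1 of 9 higher). The hepatocyte markers had a median of 0.11 with 0 of 8 beyond 1.5-fold. ER stress genes were higher in 9 of 17 cases and lower in 0 (median 0.96, percentile 100), with Hyou1 (1.48), Chac1 (1.31) and Creld2 (1.30) next to Sdf2l1. The within-pair median was 0.35, with 3 genes higher. Of 14 male-biased genes, 8 were higher and 0 lower (median 0.75, percentile 100, within-pair 1.01), including Nudt7 (2.08) and Gadd45g (2.02). The 6 female-biased genes had a median of -0.61 (percentile 0, within-pair -0.23), with Cyp17a1 and Fmo2 lower but Cyp2c69 higher (2.34).

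Of 25 genes of amino acid and urea metabolism, 9 were at least 1.5-fold lower in HFD and 0 higher (median -0.48, percentile 0, within-pair -0.63). They included Asns (-1.44), the urea cycle genes Asl (-1.37) and Cps1 (-1.36, 2261 against 5804 CPM) and Got1. Of 22 xenobiotic genes, 6 were lower and 1 higher (median -0.30, percentile 0, and -0.15 with TMM factors), with Cbr1 (-1.19), Sult1a1 (-1.13) and Por (-1.10) after Cyp3a11. The within-pair median was 0.13 with 3 higher and 5 lower and a mean on the other side of 0. Lipid genes went both ways. In lipogenesis (median 0.27, from 0.17 to 0.42 with other scalings, 5 higher and 1 lower of 18), Pklr (1.63) and Fasn (1.29) were higher while Scd1 was lower. In fatty acid oxidation (0.24, from 0.15 to 0.40 with other scalings, 5 higher and 4 lower of 27), Vnn1 was higher (1.21) and Cyp4a14 (-1.84) and Cyp4a10 (-1.14) lower. The lipid droplet list (0.20, 4 higher and 1 lower of 15) was led by Plin2, which coats lipid droplets, at 881 against 353 CPM (1.32), and Fitm1 (1.29). In the lipoprotein list 3 of 18 genes were lower, among them Apoa4 and Apoa5 (-0.69), and the median of -0.15 moved to 0.00 with TMM factors. Within-pair medians were 0.15 for lipogenesis, 0.48 for fatty acid oxidation (11 higher and 0 lower), -0.03 for lipid droplet (mean 0.24) and -0.12 for lipoprotein genes. Cyp4a14 followed the library pairs, with 2771 CPM in ND and 2064 CPM in LMS-K against 773 CPM in HFD and 757 CPM in S-K.

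The other functional lists lay inside the central 95% of random lists in HFD over ND, as did the lipid droplet list (percentile 89.22). Medians were 0.21 for inflammation genes (Ccl5 0.90), 0.14 for oxidative stress genes and 0.17 for acute phase genes (Orm2, Saa3 1.96, Orm1 1.44), the last turning to -0.08 without genes of large families. The median was 0.08 for matrix genes (Acta2 -0.79, Tgfb1 0.64) and turned to -0.01 with TMM factors from genes at 10 CPM or more. For bile acid (-0.02, Akr1d1 -1.30, Slco1a1 1.27), glucose (-0.03, Pck1 -1.41, Tat -0.89), clock (0.02, Cry1 -1.32, Dbp 1.22) and early-response and heat shock genes (-0.02, Hspa1b 1.72), members went both ways and the sign of the median differed between scalings. Means of 0.07, -0.14, -0.12 and 0.06 stood beside these medians, in the same order. Among markers of other cells, medians were 0.43 for lipid-associated macrophages (Fabp5 0.71), 0.70 for erythroid genes (Alas2 1.30, Hba-a2 1.11), 0.51 for lymphocytes (Ccl5, Igkc 0.51), 0.24 for cholangiocytes (Sox9 -0.58, Spp1 0.50) and -0.46 for portal fibroblasts and smooth muscle (Acta2, Tagln -0.46). Of these, the lymphocyte (percentile 94.47) and cholangiocyte (70.64) medians lay inside the random lists. The lipid macrophage (98.95), erythroid (99.84) and portal fibroblast and smooth muscle (0.615) medians lay outside. Single measured members were Ccnd1 for proliferation (1.59), Plac8 for monocytes and neutrophils (0.54) and Car3 for adipocytes, which hepatocytes also express (2861 against 716 CPM). For pancreas and gut they were Cela1 (1.46) and Fabp2 (0.77). The median of all genes in HFD over ND was 0.10 and became 0.25 with TMM and 0.22 with DESeq2 factors, against which the list medians should be read. Of the genes at least 2-fold apart, 74% were higher in HFD, against 87% with TMM, 84.9% with DESeq2 factors and 62.8% with TMM factors from genes at 10 CPM or more.

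**Figure D1:**
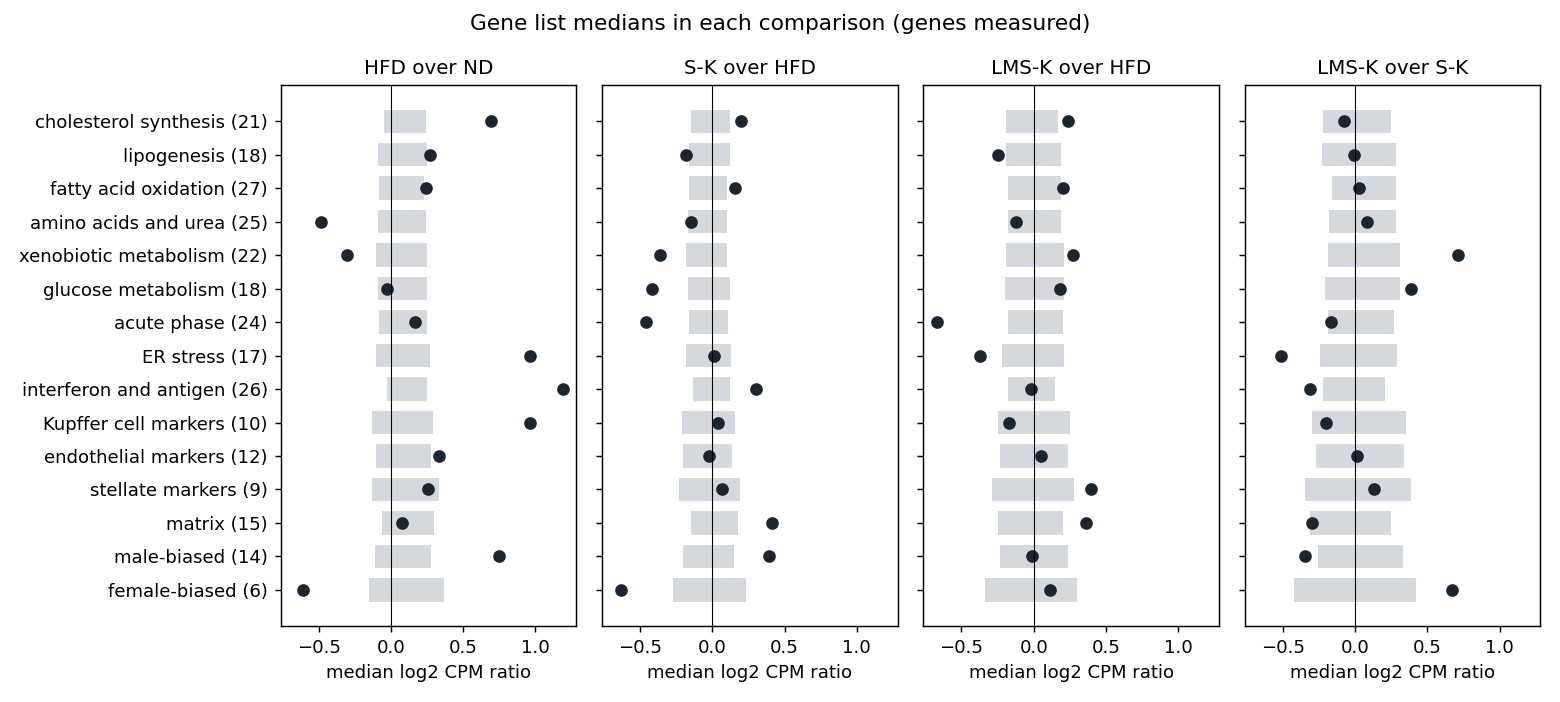
Median log2 CPM ratio of 15 gene lists in the 4 comparisons (points, with the number of measured genes in brackets), against the central 95% of 10000 random lists matched on expression (grey bars). Interferon and antigen genes (1.19), ER stress genes (0.96) and Kupffer cell markers (0.96) lay farthest above the bars in HFD over ND, and acute phase genes lay below them in S-K over HFD (-0.46) and LMS-K over HFD (-0.67).

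The S-K section was compared with the HFD section, its pair among the libraries, for what goes with spontaneously fermented kimchi on the same diet. Metallothionein genes and several other acute phase genes were lower in S-K, as were Scd1, Rgs16 and several genes of xenobiotic metabolism. Several genes of smooth muscle, matrix and cholangiocytes were higher, together with Id1 and Id3, targets of bone morphogenetic protein signalling. Of 6976 genes, 44 were at least 2-fold higher and 57 at least 2-fold lower, and 93.5% lay within 1.5-fold. Among the higher genes at 20 CPM or more were Dpt, which encodes a matrix protein (26 against 4.80 CPM, 2.44), Gsn for the actin-severing gelsolin (2.37), Id1 (2.14) and the urinary protein gene Mup17 (1.97). Others were Id3 (81.5 against 22.6 CPM, 1.85), G0s2, an inhibitor of lipolysis (281 against 85.4 CPM, 1.72), Egfr (1.67) and Fabp5 (1.67). The lowest ratio was that of Mt2 (chromosome 8, 94172618 to 94173567), with 13.3 CPM in S-K and 223 CPM in HFD (-4.07, -4.16 to -3.98), and Mt1 beside it (94178883 to 94180327) stood at 52.8 and 407 CPM (-2.95, -2.99 to -2.90). Rgs16 (-3.35), Scd1 (-2.53), Lcn2 (-2.05), the heat shock gene Hspa1b (-1.89), Slco1a4 (-1.80) and Gadd45g (-1.62) were the other genes of this group.

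In the acute phase list, 11 of 24 genes were at least 1.5-fold lower in S-K and 0 higher (median -0.46, percentile 0), with Orm3 (-2.07) after the metallothioneins. Xenobiotic genes were lower in 5 of 22 cases and higher in 0 (-0.36, percentile 0), including Gstt3 (-1.42), Cyp3a11 (155 against 402 CPM, -1.38) and Fmo5 (-1.25). The median was -0.17 without genes of large families. The glucose list had a median of -0.42 (percentile 0) with 3 of 18 genes lower and 2 higher, Irs2 (0.82) and Pck1 (0.69). Lipogenic genes were lower in 4 of 18 cases and higher in 1 (-0.18, percentile 1.35), with Thrsp (-1.35) and Pklr (-1.15) after Scd1. Male-biased genes had a median of 0.39 (4 higher and 1 lower of 14, percentile 100), with Selenbp2 (1.19) and Nudt7 (0.88) higher. Female-biased genes had one of -0.63 (1 higher and 3 lower of 6, percentile 0), with Cyp2c69 (-2.48) and Cyp2a4 (-1.40) lower. Medians were small but above the random lists for interferon and antigen genes (0.30, Ifi47 0.78), cholesterol synthesis (0.20, Sqle 1.37, Hsd17b7 0.88) and fatty acid oxidation (0.16).

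Of 15 matrix genes, 7 were at least 1.5-fold higher in S-K than in HFD and 0 lower (median 0.41, percentile 100), led by Acta2, smooth muscle actin, with 18 against 1.40 CPM (3.69, 3.44 to 3.94), Tagln (2.16), Col1a1 (1.93) and Col1a2 (1.44). The markers of portal fibroblasts and smooth muscle were higher with them (3 of 3 higher, median 2.16, percentile 99.98), and Acta2 and Tagln belong to both lists. The cholangiocyte markers Spp1 (0.97) and Sox9 (0.89) were also higher (median 0.89 over 3 genes). Without the 5% of spots richest in smooth muscle genes, the matrix median was 0.36 and that of portal fibroblast and smooth muscle markers 1.55. These spots were chosen on the portal fibroblast and smooth muscle list itself. The 2 medians therefore cannot show independently where in the section the difference lies. With each spot weighted equally, the matrix median was 0.88, and the share of higher genes among those at least 2-fold apart was 57% against 43.6%. Pairs of quadrants of S-K differed at least 2-fold in 1 to 19 genes. Kupffer cell (0.04), endothelial (-0.02), stellate (0.07), lipid droplet (0.06), lipid macrophage (0.06), ER stress (0.01, with a mean of -0.02), inflammation (-0.03), oxidative stress (-0.04), bile acid (-0.06), lipoprotein (-0.05) and early-response (-0.05) lists had medians near 0, and the sign of those within 0.06 of 0 differed between alternatives for several of them. The remaining medians were -0.15 for amino acid, -0.18 for hepatocyte, -0.19 for clock, -0.36 for erythroid and 0.24 for lymphocyte genes. Ccnd1 stood at 1.21, Car3 at 0.30, Plac8 at 0.33, Cela1 at 0.07 and Fabp2 at -0.21.

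The LMS-K section was compared with the HFD section for what goes with starter-fermented kimchi on the same diet, across the library pairs. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and the transcriptional repressor gene Bcl6 were among the highest ratios in LMS-K. Many acute phase genes, the metallothioneins among them, and several ER stress genes were lower, and Scd1 was lower as well. Cyp3a11, lower in S-K than in HFD, was higher in LMS-K, together with other genes of xenobiotic metabolism. Of 6952 genes, 67 were at least 2-fold higher and 102 at least 2-fold lower, and 87.8% lay within 1.5-fold. Cyp7a1 (chromosome 4, 6265612 to 6275632) stood at 479 CPM (474 to 484) against 82.5 CPM (80.8 to 84.3), a log2 ratio of 2.54. The clock repressor gene Cry1 stood at 34 against 6.53 CPM (2.38) and Bcl6 (chromosome 16, 23965050 to 23988866) at 170 against 34.5 CPM (2.30, 2.24 to 2.35). Gpcpd1 (2.20), Pdk4, an inhibitor of pyruvate oxidation (2.19), the acyl-CoA thioesterase gene Acot3 (2.16), Rapgef4 (2.07) and the retinoic acid hydroxylase gene Cyp26b1 (1.80) followed. Among the lowest ratios were Mt2 (16.1 against 223 CPM, -3.79), Orm2 (-3.36), Foxq1 (-2.89), Mt1 (58.7 against 407 CPM, -2.79), the hepatocyte transcription factor gene Onecut1 (-2.31), Cyp2u1 (-2.15), Derl3 (-2.07) and Klhdc7a (-2.06).

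Acute phase genes were lower in 13 of 24 cases and higher in 0 (median -0.67, percentile 0, and -0.39 without genes of large families), including Lcn2 (-2.02). ER stress genes were lower in 7 of 17 cases and higher in 0 (-0.37, percentile 0.05), with Sdf2l1 (-1.88), Chac1 (-1.14) and Hyou1 (-1.07). The lipogenesis median was -0.25 (percentile 0.52) with Scd1 at -1.79, and that of erythroid genes -0.70 with Hba-a2 (-1.35) and Alas2 (-1.28) lower. Xenobiotic genes were higher in 7 of 22 cases and lower in 2 (median 0.27, percentile 99.44), with Ces1d (1.74), Por (1.58) and Cyp3a11 (1.36) higher and Gstp1 lower (-1.01). The median was 0.04 with TMM and 0.02 with DESeq2 factors. In fatty acid oxidation 9 of 27 genes were higher and 0 lower, among them Pdk4, Acot3, Acot1 (1.71) and Cyp4a14 (1.42). The median of 0.20 turned to -0.03 with TMM and -0.05 with DESeq2 factors. The cholesterol synthesis median of 0.24 (3 higher and 1 lower of 21, Msmo1 0.79) likewise turned to -0.01 with DESeq2 factors. Matrix genes were higher in 5 of 15 cases and lower in 0 (0.36, percentile 99.99), with Acta2 (7.25 against 1.40 CPM, 2.38), Tagln (1.86) and Vim (0.97). Portal fibroblast and smooth muscle markers had a median of 1.86 (3 of 3 higher) and stellate markers one of 0.40 (1 of 9 higher). The matrix median was 0.14 and the stellate median 0.17 with TMM factors. Without the 5% of spots richest in smooth muscle genes, the matrix median was 0.15 and that of portal fibroblast and smooth muscle markers 0.98. As in S-K, the spots were chosen on the marker list itself, so these medians cannot show independently where the difference lies.

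In LMS-K over HFD, bile acid genes had a median of 0.07 with Cyp7a1, Akr1d1 (1.29) and Cyp8b1 (0.80) higher and Nr0b2, a repressor of Cyp7a1, lower (-1.16). Glucose genes had a median of 0.18, which turned to -0.05 with TMM factors, with Igfbp1 (1.07) and G6pc (0.88) higher and Slc2a2 lower (-0.87). Clock genes went both ways (0.06), Cry1 higher and Dbp (-1.80) and Nr1d1 (-1.60) lower. Medians inside the random lists were also found for interferon and antigen (-0.02), Kupffer cell (-0.17), male-biased (-0.01, Selenbp2 -1.56), female-biased (0.11), amino acid (-0.12), lipid droplet (-0.01, G0s2 1.57), lipoprotein (0.04), inflammation (-0.31), oxidative stress (-0.19), early-response (-0.14), endothelial (0.05, with a mean of -0.07), hepatocyte (-0.15), lymphocyte (-0.03), lipid macrophage (-0.08) and cholangiocyte genes (0.17). Ccnd1 stood at -0.83, Plac8 at 0.65, Car3 at -0.43, Cela1 at -0.67 and Fabp2 at -0.37. The median of all genes was -0.00 and moved to -0.24 with TMM and -0.26 with DESeq2 factors, and the medians of bile acid, clock, lipoprotein, female-biased, endothelial and cholangiocyte genes were below 0 with these factors. The share of higher genes among those at least 2-fold apart was 39.6%, against 14.7% with TMM and 13.9% with DESeq2 factors. With TMM factors from genes at 10 CPM or more, the median of all genes was 0.01 and this share 42.6%. The TMM and DESeq2 factors that shift the medians also draw on genes under 10 CPM.

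LMS-K was set against S-K to ask how the kimchi sections differ, again across the library pairs. Many xenobiotic genes and several glucose and clock genes were higher in LMS-K, whereas several ER stress, male-biased and interferon genes were lower. Of 7025 genes, 150 were at least 2-fold higher and 158 at least 2-fold lower, and 78.7% lay within 1.5-fold. Among genes at 20 CPM or more, Bcl6 had the highest ratio, with 170 CPM in LMS-K and 12.8 CPM in S-K (3.73, 3.63 to 3.82), followed by Acot3 (2.90), Rgs16 (2.84), Cyp3a11 (1034 against 155 CPM, 2.74), the clock-controlled deubiquitinase gene Usp2 (2.73) and Slco1a4 (2.64). Onecut1 (-2.84), Selenbp2 (79.2 against 534 CPM, -2.75), Derl3 (-2.72), the clock repressor gene Nr1d1 (-2.46), Orm2 (-2.40) and Sdf2l1 (-2.19) were lowest among genes at 20 CPM or more with separate quadrant ranges. Of 22 xenobiotic genes, 12 were higher and 1 lower (median 0.71, percentile 100), with Ces1d (2.20) and Gsta3 (1.48) higher and Gstp1 lower (-1.52). The median was 0.46 with TMM factors. Glucose genes were higher in 6 of 18 cases and lower in 1 (0.39), among them Igfbp1 (1.26), Gys2 (1.15) and Slc37a4 (1.03), and clock genes in 6 of 15 with 2 lower (0.39, Cry1 2.40). With TMM factors these medians were 0.14 and 0.15. Female-biased genes had a median of 0.67 (3 of 6 higher, Cyp2a4 1.40), which was 0.36 with each spot weighted equally.

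In LMS-K over S-K, ER stress genes were lower in 7 of 17 cases and higher in 2 (-0.51, percentile 0.02), with Hyou1 (-1.26), Creld2 (-1.13) and the chaperone gene Hspa5 (-1.08). Male-biased genes were lower in 5 of 14 (-0.35, Nudt7 -1.43, Hsd3b5 -1.26) and interferon and antigen genes in 7 of 26 (-0.31, Ifit1 -1.05, Oasl1 -0.90). Matrix genes were lower in 4 of 15 cases (Col1a1 -1.50, Acta2 -1.31), with a median of -0.30 inside the random lists (percentile 2.775). Of the lipid macrophage markers 3 of 6 were lower (-0.54, Fabp5 -1.15), and of the cholangiocyte markers 2 of 3 (-0.65). Medians were -0.17 for acute phase (Il1r1 1.30, Hp -1.27), 0.08 for bile acid (Akr1d1 2.26, Cyp7a1 1.78), -0.08 for cholesterol synthesis, -0.01 for lipogenesis (mean 0.03), 0.03 for fatty acid oxidation, -0.05 for lipid droplet, 0.07 for lipoprotein, 0.08 for amino acid, -0.15 for inflammation, 0.03 for oxidative stress and -0.11 for early-response genes (mean 0.05). For cell markers they were -0.20 (Kupffer cells), 0.01 (endothelium), 0.13 (stellate cells), 0.05 (hepatocytes), -0.27 (lymphocytes), -0.37 (erythroid) and -0.37 (portal fibroblasts and smooth muscle). Ccnd1 stood at -2.04, Car3 at -0.73, Cela1 at -0.74, Plac8 at 0.32 and Fabp2 at -0.15. The median of all genes moved from -0.00 to -0.26 with TMM and -0.29 with DESeq2 factors, and list medians between 0 and 0.13 were below 0 with these factors. The share of higher genes was 48.7%, against 14.8% with TMM, 13.3% with DESeq2 factors and 37.5% with totals without the 50 most abundant genes. With TMM factors from genes at 10 CPM or more, the median of all genes was 0.00 and this share 49.7%.

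Several of the HFD differences from ND were also present in both kimchi sections. At least 2-fold higher than ND in all 3 fat-fed sections were, among others, Sqle (10.7, 27.6 and 16.8 CPM in HFD, S-K and LMS-K against 0.514 CPM in ND), Hsd17b6, Cyp51, Selenbp2, H2-Eb1, Msmo1, Nudt7 and Cd74, the invariant chain of MHC class II (237, 287 and 361 against 77.1 CPM). At least 2-fold lower in all 3 were Cyp17a1 (14.1, 16.3 and 16.5 against 144 CPM), Scd1, Got1, Apoa4, Sds, Cps1 and Arg1, which carry steroid, lipid and amino acid metabolism. Genes of this paragraph outside the naming rule were chosen after their values were seen. For the 154 genes higher in HFD, the median share of the log2 difference left was 1.03 in S-K and 0.57 in LMS-K, against 0.69 and 0.70 in simulations in which the fat-fed sections were exchangeable. For the 54 lower genes the shares were 1.16 and 0.48, against 0.59 and 0.58. However, the share in LMS-K was 0.29 with selection at 1.5-fold and 0.69 with TMM factors, settings that the simulated values do not cover. When genes were selected on S-K, LMS-K kept 0.52 of the difference of the 261 higher genes and 0.33 of that of the 121 lower genes, and HFD kept 0.70 and 0.55, against 0.57 to 0.70 in the simulations. When they were selected on LMS-K, S-K kept 0.87 and HFD 0.72 over 118 higher genes, and 0.89 and 0.48 over 58 lower genes, against 0.57 to 0.71. S-K lies across the library pairs from ND, as HFD does, and LMS-K lies within a pair with ND.

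**Figure D2:**
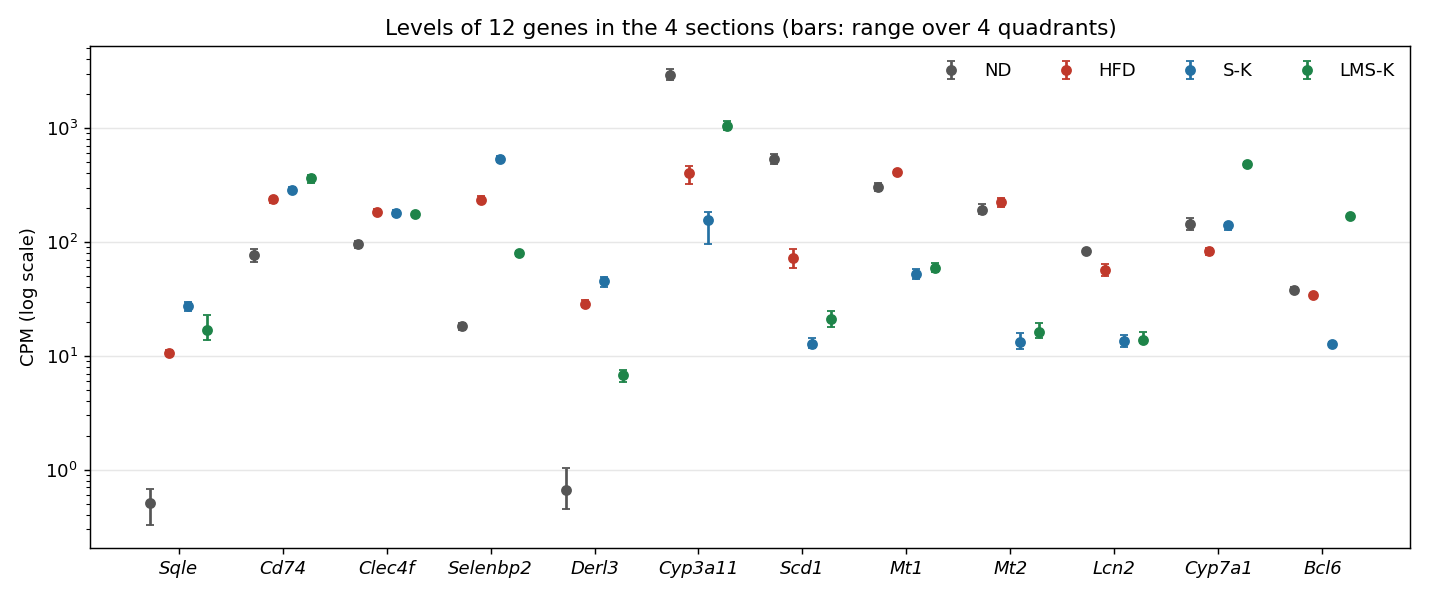
CPM (log scale) of 12 genes, chosen after their values were seen, in the 4 sections, with bars for the range over 4 quadrants of each section. Mt1, Mt2 and Lcn2 lay lower in both kimchi sections (Mt2 at 13.3 and 16.1 CPM) than in ND and HFD (190.6 and 222.5 CPM), Cyp3a11, Selenbp2 and Derl3 differed between the kimchi sections, and Cyp7a1 and Bcl6 were highest in LMS-K.

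The portal-to-central axis was read from genes not used to place the spots. All 19 measured central genes were higher in the central zone in each section, with a median log2 ratio of zone 5 over zone 1 of 2.34 in ND (2.11 to 2.44), 2.48 in HFD (2.40 to 2.52), 2.18 in S-K (2.07 to 2.29) and 1.62 in LMS-K (1.57 to 1.68). Of 24 portal genes, 21 were higher in the portal zone in each section, with medians of -0.82, -1.14, -1.08 and -0.82. Rgn, which encodes regucalcin, had central gradients of 3.64, 2.75, 3.03 and 2.42 in ND, HFD, S-K and LMS-K, and the retinaldehyde dehydrogenase gene Aldh1a1 of 1.72, 1.88, 1.65 and 1.54. Car3 (1.44, 1.84, 1.02 and 1.16) and Gstm1 (1.23, 1.60, 1.52 and 0.85) were less steep. On the portal side, the hemopexin gene Hpx had gradients of -1.52, -1.54, -1.42 and -1.49. Those of Cps1 were -0.69 in ND and -1.39, -1.29 and -1.23 in the fat-fed sections. Those of the gluconeogenic Pck1 were -0.93, -1.56, -1.07 and -0.70, those of Uox -0.70, -1.20, -1.08 and -0.91, and those of Gnmt -0.41, -0.44, -0.11 and -0.13. Across 2032 genes that were not landmarks, gradients correlated at 0.919 to 0.956 between sections. In ND, HFD, S-K and LMS-K, 84, 107, 90 and 71 genes were at least 2-fold more central and 35, 45, 41 and 44 at least 2-fold more portal.

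Over whole sections, the medians of the held-out central genes lay outside the random lists in HFD over ND (percentile 98.12), S-K over HFD (0.355) and LMS-K over S-K (99.88), and those of the portal landmarks in all 4 comparisons (0 to 2.25). The medians of the held-out portal genes and of the central landmarks lay inside the random lists in all 4. In HFD over ND the held-out central genes had a median of 0.27 (Lgals1 1.39, Lect2 1.08) and the held-out portal genes 0.01, with a mean of -0.19 (3 higher and 6 lower of 24, with Apoa4, Pck1, Asl and Cps1 lower). The medians of these lists were -0.23 and -0.12 in S-K over HFD (Tbx3 1.42, Axin2 1.32), 0.17 and -0.18 in LMS-K over HFD (Cyp7a1, Ftcd -1.33), and 0.45 and -0.07 in LMS-K over S-K. The value of 0.17 turned to -0.05 with TMM and -0.07 with DESeq2 factors. Beside the medians, the 19 held-out central genes had a mean of -0.00 in S-K over HFD, with 3 higher and 1 lower. In LMS-K over S-K their mean was 0.16, with 7 higher and 5 lower. Of the landmark lists, the central one had medians of 0.41, -0.04, -0.18 and -0.30 in the same comparisons, and the portal one -0.16 (mean 0.06), -0.35, -0.79 and -0.47, with Hsd17b6 higher and Sds and Etnppl lower in HFD than in ND and Ctsc lower in LMS-K than in HFD (-1.31).

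**Figure D3:**
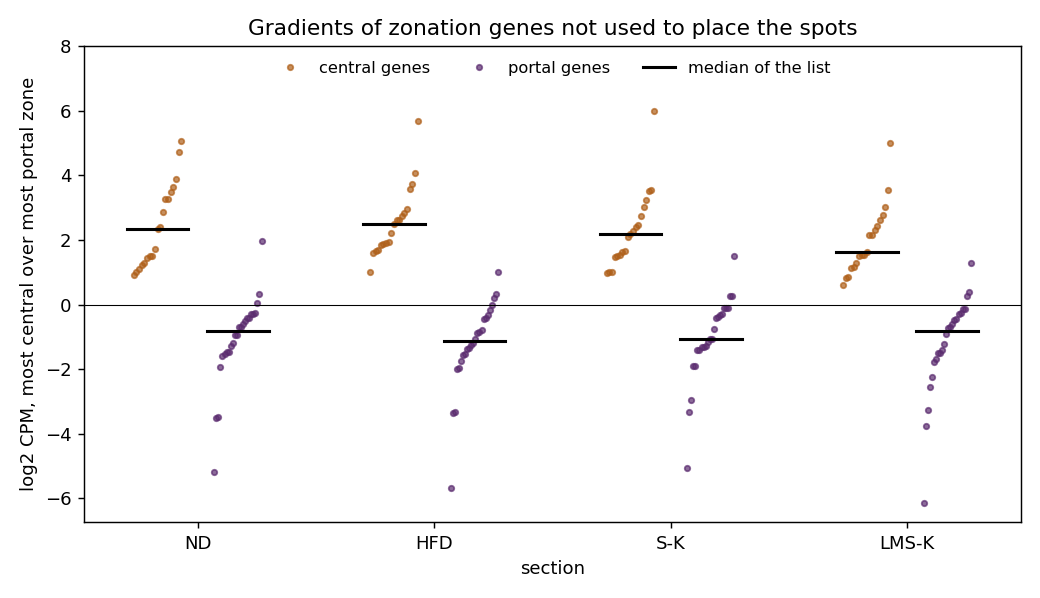
Log2 CPM ratio of the most central over the most portal zone for 19 central and 24 portal genes held out from the placement of spots (points, 1 per gene) in each section, with the median of each list as a line. Central medians ran from 1.62 in LMS-K to 2.48 in HFD and portal medians from -1.14 in HFD to -0.82 in ND and LMS-K.

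Most differences between sections were similar at both ends of the axis. Across genes, ratios in zone 1 and zone 5 correlated at 0.845 in HFD over ND (2217 genes), 0.822 in S-K over HFD (2248), 0.853 in LMS-K over HFD (2245) and 0.915 in LMS-K over S-K (2138). In the same order, 9, 12, 14 and 9 genes differed at least 2-fold in their gradient. In HFD over ND, Scd1 was lower by more at the central end (-4.17 against -2.58 at the portal end), as was the hepcidin gene Hamp (-2.78 against -1.51). Cyp3a11 was lower at both ends, by more at the portal one (-3.46 portal, -2.31 central). G0s2 was lower mainly at the portal end (-1.49 and -0.12), Adh4 was higher mainly at the portal end (2.16 and 0.76), and Igfbp2 was higher at the portal (0.93) and lower at the central end (-0.73). In S-K over HFD, G0s2 was higher mainly at the portal end (2.40 and 0.82), as was Mup11 (1.77 and 0.57), and Serpina12 mainly at the central end (0.47 and 1.98). The sterol gene Msmo1 was higher at the portal (0.79) and lower at the central end (-0.54). In LMS-K over HFD, Hamp was higher mainly at the central end (0.68 and 2.46), whereas Nr0b2 (0.03 and -2.01), Pklr (0.30 and -1.67) and Hsd17b13, a lipid droplet protein gene (0.01 and -1.56), were lower mainly at the central end. In LMS-K over S-K, Msmo1 was higher at the central end (-0.37 and 1.30), and Serpina12 (-1.35 and -2.94) and Gldc (-0.63 and -1.93) were lower mainly there.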

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

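The tests on the pairing of the sections were chosen after the result was seen.

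Some genes lay on opposite sides of HFD in the kimchi sections, which was not tested as a difference because each diet has 1 section. The xenobiotic list had a median log2 ratio over HFD of -0.36 in S-K and 0.27 in LMS-K, of which the latter was 0.04 with TMM factors. Cyp3a11 stood at -1.38 in S-K and 1.36 in LMS-K. Akr1c19, a member of the aldo-keto reductase family chosen after its values were seen, stood at -1.11 and 1.10, with 110.9 CPM in ND, 101.7 CPM in HFD, 47 CPM in S-K and 218 CPM in LMS-K. Selenbp2 went the other way, with 1.19 in S-K and -1.56 in LMS-K.

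Cyp3a11 and Selenbp2, but not Akr1c19, were among 30 genes at least 2-fold apart between ND and LMS-K on one side and HFD and S-K on the other, with Derl3, Orm2, Onecut1 and Cry1. The limits of 10 CPM and 2-fold put a floor under the differences of the 30 genes. Their lowest difference, 6.56 CPM, therefore cannot decide on probe background. Among 1306 genes taken as not expressed in liver, the highest difference between the pairs was 6.12 CPM (Olfr1033) and the median 0.115 CPM. The median of the 30 genes was 36.1 CPM. Background of the measured size is thus argued against for those of them well above 6.12 CPM, whereas size cannot decide for those near it. Of the 30 genes, 18 were higher in HFD and S-K, where summed background was lower (160 and 129 CPM, against 311 and 317 CPM in ND and LMS-K). This direction argues against background for these 18 genes as a set. A library preparation shared by each pair cannot be told apart from the diets: in 1869 genes at 50 CPM or more, all 4 sections correlated best with their partner (0.971 and 0.979, against 0.941 to 0.965 for other pairs), and no run or slide is given in the sources used here. Time of collection stays open too, since 5 clock genes that peak at night had a median 0.79 above that of 6 that peak by day (0.72 and -0.08, ND and LMS-K over HFD and S-K), outside the -0.49 to 0.44 of random gene sets, and clock genes could also differ with diet. The diets themselves remain a candidate explanation that was not tested.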

How the results depend on the processing

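TMM factors from genes at 10 CPM or more, sections without the spots richest in smooth muscle genes, and tables without genes of large families were chosen after seeing the data. For the 60 ratios of genes named by size, the direction was kept and the difference stayed at least 2-fold in all 698 values under 12 alternatives, whereas single genes named from lists were not followed. Of 1552 list medians under alternatives, 1082 stayed within their spread, 466 moved beyond it and 4 changed the sign of a median that lay outside the central 95% of random lists. The number of lists outside random lists stayed within 1.5 times in 13 of 13 alternatives. Scaling factors shift a list and its random lists alike, so under them this number is nearly fixed by construction. No paired analysis was possible because each diet has 1 section. Leaving out mitochondrially encoded genes was not run, because the tables used here hold none. Depth limits low genes most: the further genes that a count without a filter takes in all lie under 10 CPM, where counting error and probe background weigh most.

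For HFD over ND, the count of higher genes was 241 with TMM factors, 410 with no filter (and 4176 lower) and 67 at 50 CPM or more, where fewer genes are counted. For S-K over HFD it was 794 higher and 1067 lower with no filter, 13 and 27 at 50 CPM, and 77 higher with each spot weighted equally. For LMS-K over HFD, higher and lower genes numbered 38 and 221 with TMM factors, 37 and 229 with DESeq2 factors, 3934 and 247 with no filter, and 30 and 46 at 50 CPM. For LMS-K over S-K they numbered 70 and 403, 68 and 443, 4195 and 338, and 77 and 67 in the same order. With TMM factors from genes at 10 CPM or more, they numbered 69 and 93 in LMS-K over HFD. In LMS-K over S-K they numbered 152 and 154 with these factors. Among medians outside the random lists, those that changed sign were of LMS-K over HFD for cholesterol synthesis (-0.01 with DESeq2 factors) and fatty acid oxidation (-0.03 with TMM, -0.05 with DESeq2 factors), and of HFD over ND for lipoprotein genes (0.00 with TMM factors). These follow from the shift that the factors give every gene. Medians inside the random lists also changed sign, such as those of acute phase genes in HFD over ND and of glucose, bile acid and clock genes in LMS-K over HFD.

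The share of the HFD over ND difference left in S-K for higher genes was 1.08 at 50 CPM. In LMS-K it was 0.46 with selection at 1.5-fold, 0.43 with TMM factors and 0.51 with TMM factors from genes at 10 CPM or more for higher genes, and 0.29 with selection at 1.5-fold and 0.69 with TMM factors for lower genes. With 3 zones, whose ends lie closer together, central gradients were 1.98 in ND, 1.84 in HFD, 1.79 in S-K and 1.23 in LMS-K, portal ones -0.65, -0.93, -0.86 and -0.66, and genes with zone-dependent differences numbered 5 in S-K over HFD and 9 in LMS-K over HFD. With scores averaged over neighbours, central gradients were 2.38 in HFD and 1.46 in LMS-K, and portal ones -0.77 in ND, -1.03 in S-K and -0.76 in LMS-K. With even landmarks, portal gradients were -0.79 in ND, -1.10 in HFD and -1.04 in S-K. With pooled limits between zones, the central gradient was 2.03 in LMS-K and the portal ones -0.90 in ND and -1.10 in HFD. With spots thinned to 3000 UMIs, central gradients were 2.26 in HFD, 1.98 in S-K and 1.46 in LMS-K, and portal ones -0.76 in ND, -1.07 in HFD and -0.99 in S-K. The cause was not tested for those moves that no construction explains.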

Other observations

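All tests here were chosen after the result was seen, except the test of the metallothionein genes within zones.

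Some gene groups differed in their place along the axis. Cholesterol synthesis genes had a median log2 ratio of the central over the portal zone of 0.16 in ND, -0.32 in HFD, -0.87 in S-K and -0.34 in LMS-K, and in S-K 15 of 21 were at least 1.5-fold higher at the portal end. Matrix genes were at -0.10 in ND and 0.06 in HFD, against -0.74 in S-K and -0.33 in LMS-K. Kupffer cell markers were portal in ND (-0.86, 10 of 10 at least 1.5-fold), HFD (-0.68, 8 of 10) and LMS-K (-0.69, 7 of 10), and less so in S-K (-0.38, 1 of 10).

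Of 7151 genes, those at least 2-fold higher in both kimchi sections than in ND and HFD numbered 7, with Acta2 (18 and 7.25 CPM against 2.42 and 1.40) and Nrep (39 and 48.2 CPM against 4.09 and 15.1) among them, and 5 were lower (Mt1, Mt2, Lcn2, Scd1 and Adora1). Split by library pairs, 12 genes were higher in ND and LMS-K and 18 in HFD and S-K. For ND and S-K against HFD and LMS-K, the counts were 2 and 2.

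Kupffer cell markers were higher in all 3 fat-fed sections than in ND. The within-pair median of LMS-K over ND was 0.82 (0.61 to 0.90 on resampling genes, which covers no spread between sections), so these partners differed. This ratio is part of the pattern itself, and all 3 ratios share the ND section. It therefore cannot decide whether library preparation contributed. A lower share of hepatocytes would raise the 21 endothelial and stellate markers alike, but the 10 Kupffer cell markers lay above them by at least 0.46 (0.24 to 0.56, in LMS-K). The endothelial and stellate markers themselves had medians over ND of 0.31 in HFD, 0.28 in S-K and 0.35 in LMS-K. A lower share of hepatocytes is thus argued against as the whole cause, but not as a part of it. With pooled zones weighted equally, the median for HFD over ND was 1.03. The landmarks that place the spots differed between these sections (Hsd17b6 2.89, Sds -1.63), so a pooled zone need not be the same place in both. In zones placed within each section, the portal and central medians over ND were 0.90 and 1.03 in HFD. They were 0.75 and 1.17 in S-K and 0.74 and 0.87 in LMS-K. A different share of zones is thus argued against only as far as zones match between sections. More Kupffer cells or more transcript per cell on the high-fat diet may account for the higher Kupffer cell markers, a hypothesis that 1 section per diet cannot test further. A spot holds several cells, so its values cannot separate cell number from transcript per cell.

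Mt1, Mt2 and Lcn2 were lower in both kimchi sections, and kimchi intake itself was not tested as a cause. A preparation shared by each pair would leave partners alike. Mt1, Mt2 and Lcn2 were at -2.05 or lower in S-K over HFD. They were at -2.36 or lower in LMS-K over ND, a pair that shares no section with the other. However, they were picked for being at least 2-fold lower in both kimchi sections, which fixed this direction in advance. Of the other genes named lowest in S-K over HFD, Scd1 and Slco1a4 were also lower in LMS-K than in ND. Rgs16, Hspa1b and Gadd45g were higher there. The ratios therefore cannot decide on a shared preparation. A different share of zones is argued against by the value of Mt1, Mt2 and Lcn2 nearest to 0 in any zone, -1.65. Glucocorticoids raise metallothionein genes, and 5 other genes they raise (Fkbp5, Tsc22d3, Zbtb16, Per1 and Sgk1) had medians of -0.78 in S-K over HFD (4 at least 1.5-fold lower, percentile 0) and -0.35 in LMS-K over ND (percentile 0.185), where only Fkbp5 (-0.69) was at least 1.5-fold lower and Tsc22d3 stood at -0.01. A weaker glucocorticoid response may thus contribute, but these ratios were far smaller than those of Mt1 and Mt2, Fkbp5 was higher in S-K than in HFD (0.50), the limit was set after the values were seen, and a 2-fold lower median was not met.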
